A study of Mus musculus with 8 samples.

How the data were processed

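RNA sequencing had been run on 8 libraries of mouse Th17 cells on the C57BL/6J background, in 4 groups of 2 duplicates each. The transduced cells carried a control vector or a vector expressing miR-96. The genotype groups were miR-183C+/+ (wild type) and miR-183C-/- (knockout) cells, where miR-183C stands for the miR-183/96/182 cluster. Per the labels' protocols, the cells were harvested on day 4 to 5 of culture, sorted for GFP, extracted with TRIzol and selected for polyadenylated RNA with the NEBNext Ultra kit. Nothing states that the duplicates of a group were separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

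The deposited table held estimated counts per gene, not normalized. The values named genes by symbol and had 1 column per library, matched to the samples by the letter that each sample's description carries. The submitters' processing notes name bcl2fastq 2.16.0.10, STAR 2.3.0, Partek and edgeR and the mm10 build, with no role or order, and the annotation that reads were counted against is not given in the sources used here. Whether counting used strand is likewise not given. Most of the deposited estimated counts were whole to within 0.02, but 55.6% of the 13933 genes detected in knockout library 1 were not, against 6.39% to 7.41% in the other libraries. All values were rounded to whole counts before testing. Of 24453 lines, 27 had a date serial number in place of a gene symbol and were left out, which removed at most 0.243% of a library's counts. The remaining 24426 genes were joined by symbol to GENCODE mouse release 21 on GRCm38, the same assembly as mm10, and 24024 of them matched. Gene positions and 3′ UTR sequences come from that annotation, and 20506 genes had a 3′ UTR.

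Total estimated counts per library ranged from 7142429 to 12452659. Confidence intervals (95%) of count ratios are exact conditional binomial intervals, and a gene with no count in a group was set to a floor of 3 counts over the group. Intervals and floors cover counting error only.

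Differential expression was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on all 8 libraries with a term for group, TMM factors and the filterByExpr filter (minimum count 10, minimum total 15), which left 11851 genes and 4 residual degrees of freedom. The common dispersion was 0.0354, a biological coefficient of variation of 0.188. Benjamini-Hochberg adjustment was over the 11851 genes of a comparison, and a gene was called at an adjusted p under 0.05. Levels are CPM computed here with TMM-scaled library sizes, and standard errors (SE) were taken from the fold change and the F statistic. The comparisons were miR-96 vector minus control vector, knockout minus wild type, and the difference between these 2 contrasts.

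Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 44 tests of 22 lists with at least 3 tested members. The 25 lists covered the Th17 core, pathogenic and non-pathogenic programs, IL-1, IL-6 and IL-23 signalling, Foxo1-dependent genes, reported targets of miR-96 and of miR-182 and miR-183, Th1, Th2, regulatory T, Tfh, naive or memory, B, myeloid, CD8 T or NK, gamma delta T and erythroid cells, and immediate early, cell cycle, glycolysis, cholesterol, endoplasmic reticulum stress, interferon-stimulated, replication-dependent histone and mitochondrially encoded genes. The gamma delta T list had 2 tested members, the erythroid list 0 and the mitochondrial list no gene in the table, so these 3 were not tested. Matches to positions 2 to 8 of miR-96, miR-182 and miR-183 were searched in each gene's longest 3′ UTR, and the median log2 fold change of genes with a site minus that of genes with no site of the 3 was ranked among other 7-mers of the same base composition (1000 random triples for any of the 3 sites).

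Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Foxo1 and the cluster's microRNAs, the 5 largest rises and falls among called genes with an average log2 CPM of 3 or more and no overlap between libraries, up to 3 called members per list with the smallest p (otherwise 2 members of a list called as a set), the 3 most abundant members of lists of other cell types, and the 5 smallest p of the difference, with at most about 30 genes per contrast. Genes named outside it are said to have been chosen after their values were seen, and 1 gene that the rule took is not reported here.

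Alternatives were RLE and upper-quartile factors, no filter, a filter at 1 CPM in 2 libraries, DESeq2 1.42.0, a fit of the 4 libraries of a contrast, the duplicate number as a block, each library left out in turn, an estimated inter-gene correlation and fry for lists, and other site and UTR definitions. Leaving out sex-linked genes (here Y-linked genes and Xist), or both genotype libraries numbered 1, was added after seeing the data. Duplicates were compared by a chi-square test over genes, which gave 8.99 to 22.9 per degree of freedom, so no library was counted as deposited more than once. The ratio of 2 differences from the same control vector libraries was also computed in 20 simulated draws in which wild type equalled the control vector.

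The tests were run on simulated counts with 200 changed genes in 10 draws. For overexpression, over a median of 11685 genes, 45.0% of changed genes were recovered at a log2 fold of 1 and 83.4% at 2, and unchanged genes made up 7.22% of calls on average (3.10% to 11.3%). For the knockout, over 11678 genes, the shares were 43.5% and 82.9%, and unchanged genes made up 6.15% of calls (2.40% to 9.56%). The share of unchanged genes thus lay above the nominal level in both. Simulated genes varied independently of one another, without differences shared across a library, so these shares need not hold for the real calls. For the site comparison no counts were simulated: the fitted fold changes were shuffled over 11409 genes and -0.30 was added to genes with a site. The difference of medians then came back as -0.30 for overexpression (miR-96 site) and -0.32 for the knockout (any site). This checks the arithmetic and does not measure the power of the site tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the remaining steps.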

Results

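Polyadenylated RNA was sequenced from 8 libraries of mouse Th17 cells, the T helper cells that make interleukin 17. The series asks whether the miR-183/96/182 cluster, 3 microRNAs transcribed together, regulates the pathogenic function of these cells. In the first experiment cells transduced with miR-96 (2 libraries, overexpression) were set against cells transduced with a control vector (2 libraries). In the second, cells without the cluster (2 libraries, knockout) were set against wild-type cells (2 libraries). Total estimated counts were 12452659 and 10237707 in the control vector libraries, 10803163 and 7863469 with miR-96, 8487972 and 10766968 in wild type, and 7142429 and 8468661 in the knockout. Levels are given as CPM, mean ± SD with n = 2 libraries per group. The 2 contrasts share no libraries.

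The cluster lies on mouse chromosome 6 (GRCm38), with Mir182 at 30165918 to 30165992, Mir96 at 30169446 to 30169551 and Mir183 at 30169668 to 30169737, all on the minus strand and annotated as microRNA genes. Mir96 had 7 and 2 counts in the overexpression libraries and 0 in the other 6, which put overexpression at least 3.65-fold above the control vector, with the floor of 3 counts taken over the group. Mir182 and Mir183 had 0 counts in all 8 libraries, which allows up to 0.235 to 0.406 CPM by library. Libraries selected for polyadenylated RNA do not measure mature microRNAs, so these counts do not check the genotype labels, and none of the 3 genes was abundant enough to be tested. Foxo1, a transcription factor that restrains Th17 differentiation and a reported target of the cluster, lies on chromosome 3 (52268336 to 52353221, plus strand) and has 3′ UTR sites for all 3 microRNAs. Its level was 161 ± 3.70 CPM with miR-96 and 131 ± 18.8 with the control vector, a log2 fold change of 0.29 (SE 0.16, edgeR adjusted p = 0.640). In the knockout it was 138 ± 3.78 against 175 ± 26.6 CPM in wild type, a log2 fold change of -0.35 (SE 0.16, edgeR adjusted p = 0.151). Neither difference passed the test.

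Sex-linked transcripts differed between groups and between libraries of the same group. Xist, the RNA of the inactive X chromosome (chromosome X, 103460366 to 103483254), stood at 1220 and 1480 CPM in the control vector libraries, 1082 and 166 with miR-96, 1217 and 390 in wild type, and 0 and 144 in the knockout. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 1.02 and 0.0967 CPM with the control vector, 111 and 330 with miR-96, 114 and 283 in wild type, and 244 and 266 in the knockout. These genes have X-linked copies, and Xist overlaps the antisense gene Tsix, so their counts are uncertain where reads could be shared. A set of 16 genes, chosen after their values were seen, was at no more than 5% of the wild-type library 2 level in both control vector libraries. Their median level relative to wild-type library 2 was 0.412 and 0.454 in the overexpression libraries and 0.410 in wild-type library 1. The set included Il10, Ifng, Foxp3, Gzma, Jchain, Mzb1, Cd79a and Gbp2b. Of these, Gbp2b was high in the knockout (821 and 703 CPM), while Il10, Ifng, Foxp3, Gzma and Jchain were near 0 there. St6galnac1, St6galnac2, Gm15645 and BC018473, also in the set, stood in the knockout libraries at 0.615 to 2.34 times the wild-type library 2 level. Part of the set was thus low in the control vector libraries without being low in the knockout.

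**Figure D1:**
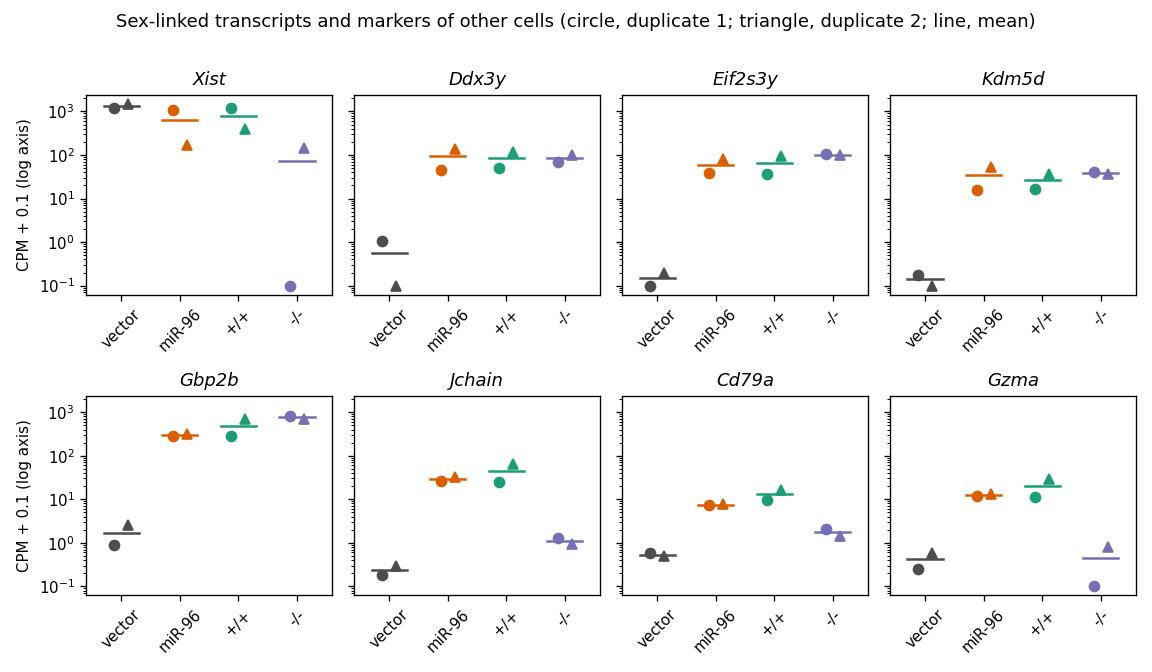
CPM + 0.1 on a log axis for Xist, Ddx3y, Eif2s3y, Kdm5d, Gbp2b, Jchain, Cd79a and Gzma in the control vector (vector), miR-96, wild-type (+/+) and knockout (-/-) groups, with a circle for duplicate 1, a triangle for duplicate 2 and a line at the group mean. Jchain stood at 0.0784 and 0.193 CPM with the control vector and at 26.7 and 31.6 with miR-96, and Xist at 0 and 144 CPM in the knockout.

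Cells carrying miR-96 were compared with control vector cells to ask what added miR-96 does to the Th17 transcriptome. Il10, an anti-inflammatory cytokine gene (chromosome 1, 131019845 to 131024974), rose from 0.426 ± 0.491 to 54.5 ± 5.95 CPM, a log2 fold change of 7.06 (SE 0.73, edgeR adjusted p = 0.0101). Gbp2b, which encodes an interferon-induced guanylate-binding protein (chromosome 3, 142594847 to 142619179), rose from 0.784 and 2.42 to 278 and 315 CPM in the libraries of each group (log2 fold change 7.58, SE 0.57, edgeR adjusted p = 0.00413). Foxp3, the lineage factor of regulatory T cells (chromosome X, 7573644 to 7595245), rose from 0.223 ± 0.0941 to 8.97 ± 1.96 CPM (log2 fold change 5.29, SE 0.72, edgeR adjusted p = 0.0459). Jchain, which joins antibody units in plasma cells, had 3 counts in the control vector libraries and 545 with miR-96, a ratio of 221 (95% interval 75.3 to 1076, edgeR adjusted p = 0.00829). The Y-linked genes Eif2s3y (ratio 1291, 231 to 51051), Kdm5d (ratio 742, 133 to 29351) and Ddx3y (log2 fold change 7.46, SE 0.91) rose as well, with edgeR adjusted p of at most 0.0204. Their levels in the 2 overexpression libraries lay apart, as for Ddx3y with 92.9 ± 67.0 CPM. Y-linked transcripts were nearly absent from both control vector libraries and present in both overexpression libraries. A difference in the sex of the source animals thus cannot be told apart from the vector in this contrast, and the rise of Y-linked genes is not evidence of a miR-96 effect.

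In all, 13 genes rose and 0 fell of 11851 tested by edgeR, with 1031 genes at an unadjusted p under 0.05 and 113 called by DESeq2 (77 higher, 36 lower). The lowest edgeR adjusted p of a gene with a negative fold change was 0.0891. The other calls included the B cell receptor gene Cd79a, at 7.47 ± 0.335 against 0.429 ± 0.0594 CPM (log2 fold change 4.07, SE 0.47, edgeR adjusted p = 0.0149). The remaining 5 were named after their values were seen and were the sialyltransferase gene St6galnac2 (18.7 ± 2.44 against 1.33 ± 0.441 CPM), the protease gene Ctse (log2 fold change 3.47, SE 0.39), Erdr1 (79.6 ± 6.35 against 29.3 ± 3.09 CPM, with no position in the annotation used here), Gm15645 (6.80 ± 0.413 against 0.0392 ± 0.0555) and BC018473. BC018473 was at 6.01 ± 0.469 CPM with miR-96 and at 0 with the control vector, at least 45.9-fold higher. Of the 13 genes, 8 remained called when sex-linked genes (Y-linked genes and Xist) were left out, which took out Eif2s3y, Kdm5d and Ddx3y. In 4252 genes (35.9%) the libraries of the 2 groups did not overlap, where chance gives 33.3%. The count fell to 0 without control vector library 1 (1254 genes at an unadjusted p under 0.05) and to 1, Gbp2b, without control vector library 2, and it was 125 (65 higher, 60 lower) without overexpression library 1 and 466 (275 higher, 191 lower) without a filter on low counts, so the lack of falls held neither without that library nor without the filter. Foxp3 also lost its call without overexpression library 2 (edgeR adjusted p = 0.0669) and wild-type library 2 (0.0914) and Ddx3y without knockout library 1 (0.0512). Over all alternatives the adjusted p ranged from 1.7e-19 (no filter) to 0.242 for Foxp3 and from 4.4e-125 (no filter) to 0.162 for Ddx3y. Foxp3 was also not called with upper-quartile factors or, though still tested, without Y-linked genes and Xist. With only the 4 libraries of this contrast 8 genes were called, 6 of them among the 13, and Cd79a, Foxp3, Kdm5d and Ddx3y were not among them.

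Genes of the Th17 program were higher as a group with miR-96, although no single member of the core list passed the test. The core list rose as a set (0 of 17 members called, 6 adjusted over the list alone, mean log2 fold change 1.04, camera adjusted p = 3.23e-08; adjusted p = 0.284 with an estimated correlation). Il1r1, the interleukin 1 receptor (chromosome 1, 40225080 to 40317257), was at 38.2 ± 9.31 against 11.9 ± 2.48 CPM (log2 fold change 1.67, SE 0.33, edgeR adjusted p = 0.199). Maf, a transcription factor that drives Il10, was at 253 ± 60.5 against 113 ± 19.1 CPM (1.17, SE 0.24, edgeR adjusted p = 0.272). Il17a, named after its values were seen, stood at 190 and 330 CPM with miR-96 and at 122 and 90.9 with the control vector (log2 fold change 1.28, edgeR adjusted p = 0.373). The pathogenic Th17 list rose as a set (0 of 18 called, 4 adjusted over the list alone, camera adjusted p = 0.0184; adjusted p = 0.326 with an estimated correlation). Il22, a cytokine gene, was at 32.2 ± 34.7 against 1.82 ± 1.20 CPM and the interleukin 7 receptor Il7r at 249 ± 79.2 against 137 ± 34.8 CPM. In the wild-type libraries, which the labels do not give as transduced with miR-96, Il17a stood at 165 and 261 CPM. Maf stood at 181 and 277 there and Il1r1 at 24.0 and 41.8, while Il7r stood at 164 and 171. Il17a, Maf and Il1r1 were thus above the control vector in wild type too, so their rise cannot be ascribed to miR-96 alone. The non-pathogenic list, with 1 of 8 called (Il10) and 2 adjusted over the list alone, rose too (camera adjusted p = 0.000294; adjusted p = 0.225 with an estimated correlation). Genes of IL-1, IL-6 and IL-23 signalling rose as a set (0 of 17 called, 1 adjusted over the list alone, camera adjusted p = 0.00408; adjusted p = 0.293 with an estimated correlation). Nfkbiz, a nuclear regulator induced by interleukin 1, had a log2 fold change of 1.07 (edgeR adjusted p = 0.387). The pathogenic list was not called without control vector library 1 (camera adjusted p = 0.220) or overexpression library 1 (0.0771), and the signalling list without control vector library 1 (0.0510) or overexpression library 2 (0.0818). Over all alternatives their adjusted p ranged from 0.0020 to 0.326 and from 0.0014 to 0.293.

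Th1, regulatory T, B cell, CD8 T and NK, and myeloid lists rose as well. Th1 genes rose as a set (0 of 14 called, 5 adjusted over the list alone, camera adjusted p = 0.000294; adjusted p = 0.262 with an estimated correlation). The cytokine gene Ifng stood at 116 ± 5.59 against 3.43 ± 4.30 CPM (log2 fold change 5.15, SE 1.02, edgeR adjusted p = 0.199) and Il18r1 at 71.6 ± 48.5 against 19.5 ± 8.16 CPM. The regulatory T list (2 of 14 called, 4 adjusted over the list alone) rose with a camera adjusted p = 0.00163, and adjusted p = 0.293 with an estimated correlation. The B cell list (1 of 6 called, 5 adjusted over the list alone, camera adjusted p = 8.56e-09; adjusted p = 0.225 with an estimated correlation) rose. So did the CD8 T and NK list (0 of 6 called, 4 adjusted over the list alone, camera adjusted p = 8.03e-06; adjusted p = 0.225 with an estimated correlation). In these lists Cd79b (log2 fold change 3.07, edgeR adjusted p = 0.0772), the granzyme gene Gzma (5.28, 0.0772) and the perforin gene Prf1 (2.80, 0.172) were not called. Neither were Ebf1, a B cell transcription factor gene (0.06, edgeR adjusted p = 0.967), and Cd8b1 (0.21, 0.911). The myeloid list rose (0 of 7 called, 0 adjusted over the list alone, camera adjusted p = 0.00647; adjusted p = 0.276 with an estimated correlation). Its most abundant members Cd68, Lyz2 and Cd14 had log2 fold changes of 0.53, 0.77 and 1.36 (edgeR adjusted p = 0.843, 0.901 and 0.731). It was not called without overexpression library 1 (camera adjusted p = 0.105) or with only the 4 libraries of the contrast (0.478), nor was the regulatory T list without control vector library 1 (0.0968). Over all alternatives the ranges of adjusted p were 1.3e-05 to 0.478 and 3.5e-05 to 0.293.

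Proliferation, sterol and interferon genes were lower as groups with miR-96. Cell cycle genes fell as a set (0 of 25 called, 16 lower adjusted over the list alone, mean log2 fold change -0.79, camera adjusted p = 6.03e-14; adjusted p = 0.326 with an estimated correlation). The mitotic kinase gene Plk1 was at 23.4 ± 13.8 against 61.1 ± 7.02 CPM (log2 fold change -1.37, SE 0.35, edgeR adjusted p = 0.367). Cholesterol synthesis genes fell as a set (0 of 18 called, 0 adjusted over the list alone, mean -0.38, camera adjusted p = 1.82e-05; adjusted p = 0.391 with an estimated correlation). Fdps was at 142 ± 40.0 against 246 ± 29.9 CPM and Cyp51 at 144 ± 31.2 against 217 ± 12.8. Interferon-stimulated genes fell as a set (0 of 13 called, 4 adjusted over the list alone, mean -0.90, camera adjusted p = 6.67e-05, and 0.326 with an estimated correlation). Their mean was -0.43 without control vector library 2. Irf7, a regulator of type I interferon, was at 5.97 ± 0.883 against 16.5 ± 1.21 CPM (log2 fold change -1.46, SE 0.30, edgeR adjusted p = 0.264). In the wild-type libraries Plk1 was at 20.1 and 17.8 CPM, Fdps at 126 and 144, Cyp51 at 141 and 156 and Irf7 at 5.61 and 8.72. These genes were thus below the control vector in wild type too, so their fall cannot be ascribed to miR-96 alone. Replication-dependent histone genes fell as a set (0 of 13 called, 0 adjusted over the list alone, camera adjusted p = 0.000888, and 0.293 with an estimated correlation). Counts within such gene families are uncertain, and whether the selection of polyadenylated RNA shaped them was not tested. The histone list was not called without control vector library 1 (camera adjusted p = 0.121), nor the interferon list without control vector library 2 (0.0676), of ranges from 3.3e-06 to 0.293 and from 7.2e-12 to 0.326 over all alternatives. In all, camera called 13 of 22 lists, 0 with an estimated correlation, and fry called 4 for movement in 1 direction and 12 for change in either direction, the Foxo1-dependent, Th2, Tfh and naive or memory lists among the 12.

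The other lists were not called with miR-96. Camera adjusted p was 0.537 for Foxo1-dependent genes (mean log2 fold change -0.08, median 0.01), 0.995 for reported miR-96 targets (mean -0.07, median 0.05) and 0.537 for reported miR-182 and miR-183 targets. It was 0.342 for Th2 genes (mean 0.53, median -0.03), 0.503 for Tfh genes, 0.457 for naive or memory genes (mean -0.14, median 0.00), 0.211 for immediate early genes, 0.503 for glycolysis and 0.369 for endoplasmic reticulum stress. The sign of mean and median differed for the Foxo1, miR-96 target and Th2 lists. The Th2 list was called without control vector library 2 (camera adjusted p = 0.000194), glycolysis without overexpression library 2 (0.0160) and endoplasmic reticulum stress without overexpression library 1 (0.0206). Over all alternatives the ranges of adjusted p were 0.00019 to 0.731, 0.016 to 0.856 and 0.021 to 0.871.

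**Figure D2:**
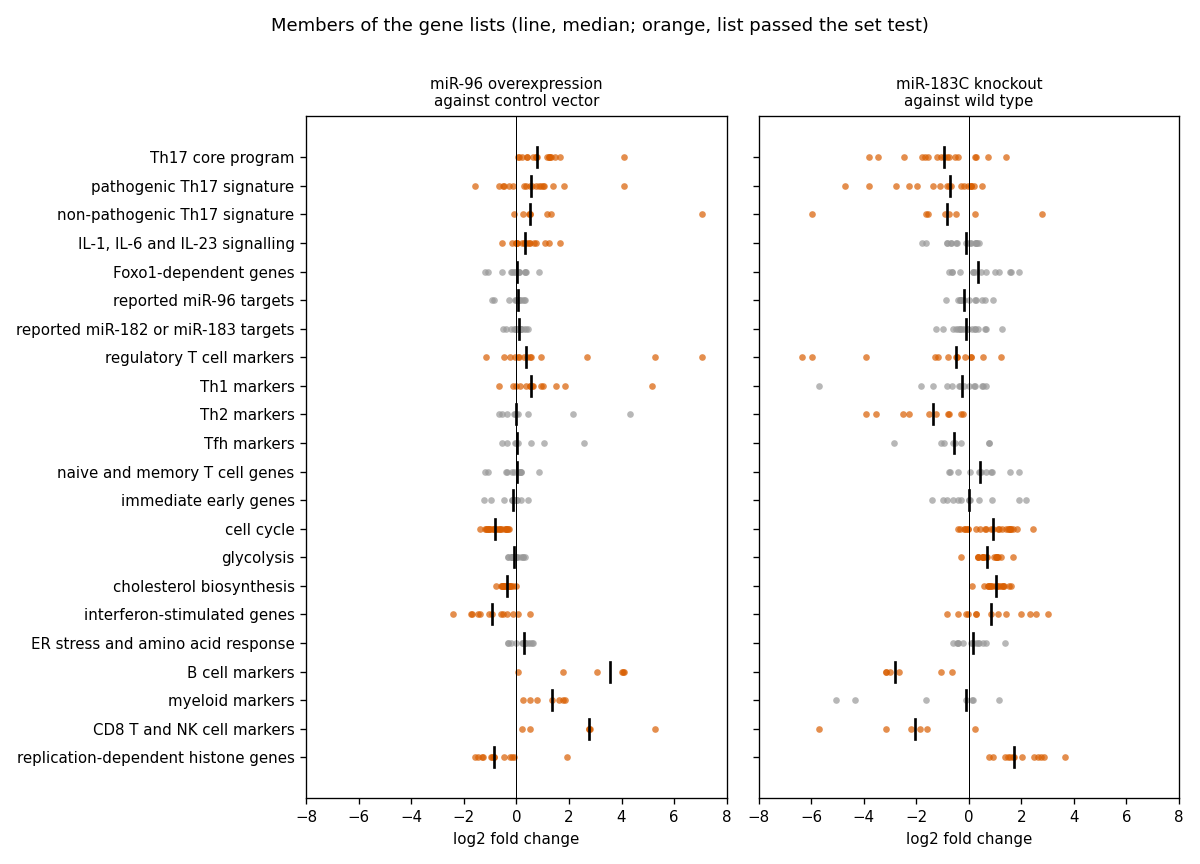
Log2 fold change of each tested member of the 22 lists, with miR-96 against control vector on the left and knockout against wild type on the right, a black line at the median, and orange for lists called by camera and grey for the others. Cell cycle genes lay mostly below 0 with miR-96 (mean -0.79) and above 0 in the knockout (mean 0.85), and Th17 core genes the other way (means 1.04 and -1.05).

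Transcripts with a 3′ UTR match to the miR-96 seed (GTGCCAA) were next compared with transcripts without a site, since a microRNA lowers its targets. The median log2 fold change with miR-96 was higher by 0.013 in the 1068 genes with a site than in the 8402 genes with no site of the 3 microRNAs (camera adjusted p = 0.896). Of 629 other 7-mers with the same base composition, 23 (3.66%) gave a value as low, and their median was 0.061. Genes with the miR-182 site (TTGCCAA) differed by 0.075 (camera adjusted p = 0.161) and those with the miR-183 site (GTGCCAT) by 0.060 (camera adjusted p = 0.161). These p were adjusted over the 7 site tests of the 2 contrasts, an adjustment added after seeing the data. The sign for miR-96 turned when genes were matched on 3′ UTR length (-0.044, as low in 26 of 629 other 7-mers, 4.13%, a rank added after seeing the data) and without overexpression library 2 (-0.016). Genes are not independent replicates.

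Knockout cells were compared with wild-type cells to ask what loss of the cluster does. Il17a and Il17f, the signature cytokine genes of Th17 cells (chromosome 1, 20730905 to 20734496 and 20777146 to 20790617), fell from 213 ± 67.9 to 19.4 ± 7.03 CPM and from 269 ± 81.8 to 48.2 ± 8.48 CPM. Their log2 fold changes were -3.45 (SE 0.37) and -2.48 (SE 0.35), with edgeR adjusted p = 0.0211 and 0.0246. Il10 fell from 94.1 ± 56.8 to 1.47 ± 1.12 CPM (log2 fold change -5.95, SE 0.64, edgeR adjusted p = 0.0211). Ifng fell from 196 ± 109 to 3.57 ± 5.05 CPM (-5.72, SE 1.04, edgeR adjusted p = 0.0254). Klf2, a transcription factor of quiescent T cells, rose from 7.31 ± 2.76 to 27.5 ± 6.32 CPM (log2 fold change 1.92, SE 0.29, edgeR adjusted p = 0.0246). The other large falls were Gzma (0.357 ± 0.505 against 20.3 ± 13.3 CPM), Jchain (1.03 ± 0.271 against 44.3 ± 28.2) and the plasma cell gene Mzb1 (1.51 ± 1.75 against 26.5 ± 15.8), with edgeR adjusted p = 0.0246, 0.0211 and 0.0248. The 5 largest rises were the laminin receptor gene Itga7 (228 ± 112 against 14.9 ± 7.66 CPM, log2 fold change 3.95), the smooth muscle myosin gene Myh11 (3.49), the receptor kinase gene Acvrl1 (3.18), the tubulin gene Tubb2b (3.04) and Mgarp (3.02), with edgeR adjusted p from 0.0246 to 0.0447. Apart from Myh11, these genes also differed widely between the control vector duplicates. Control vector libraries 1 and 2 stood at 139 and 21.7 CPM for Itga7 and at 17.4 and 2.90 for Acvrl1. They stood at 42.8 and 9.09 CPM for Tubb2b and at 16.6 and 2.71 for Mgarp. The levels of these genes thus varied without a labelled difference in genotype.

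**Figure D3:**
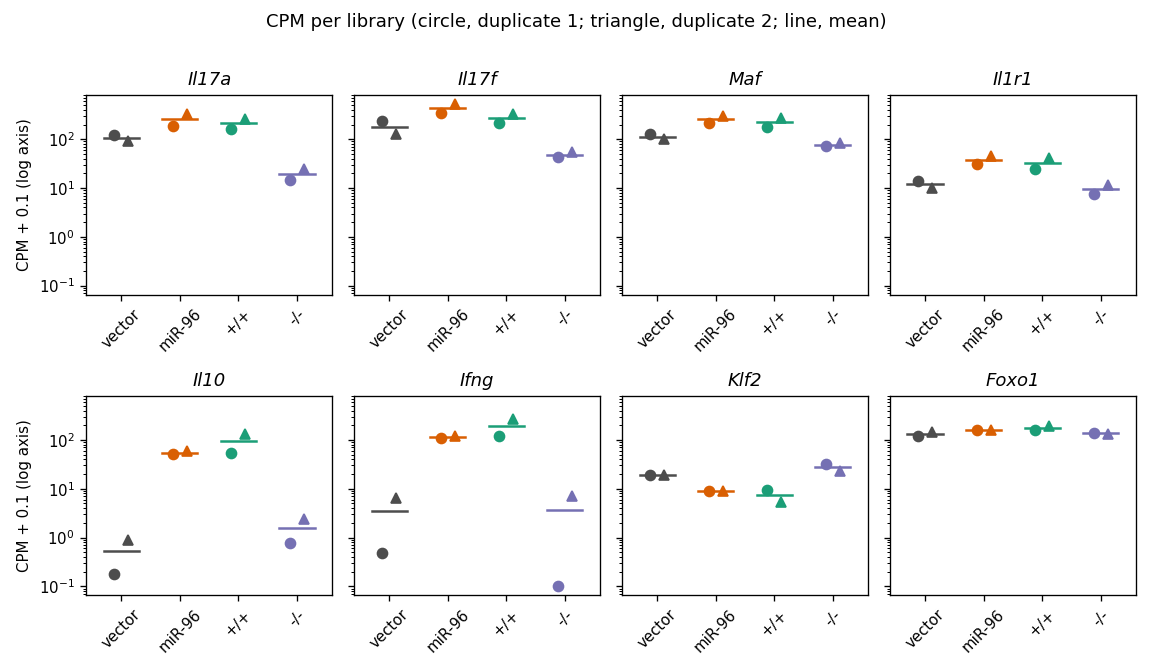
CPM + 0.1 on a log axis for Il17a, Il17f, Maf, Il1r1, Il10, Ifng, Klf2 and Foxo1 in the control vector (vector), miR-96, wild-type (+/+) and knockout (-/-) groups, with a circle for duplicate 1, a triangle for duplicate 2 and a line at the group mean. Il17a stood at 14.5 and 24.4 CPM in the knockout, below 165 and 261 in wild type, and the 8 Foxo1 values lay between 118 and 194 CPM.

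In all, 786 genes rose and 758 fell, 1544 of 11851 tested by edgeR, with 4082 at an unadjusted p under 0.05 and 2167 called by DESeq2. In 8272 genes (69.8%) the libraries of the 2 groups did not overlap, where chance gives 33.3%. The count was 0 without knockout library 1 (1864 genes at an unadjusted p under 0.05), 1 without wild-type library 2 (Jchain) and 20 without wild-type library 1. Of the 41 called genes that the rule for named genes took or that were named after their values were seen, all kept their direction in these fits, and 0, 1 and 9 kept their call, with edgeR adjusted p up to 0.295, 0.285 and 0.165. In turn 37 kept it without knockout library 2 (up to 0.122). The count was 1 without both genotype libraries numbered 1, and with upper-quartile factors Prf1 and Il12rb2 were not called.

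Th17 genes fell as groups in the knockout. Of 17 core genes, 6 fell (12 lower and 1 higher adjusted over the list alone), and the list fell as a set (mean log2 fold change -1.05, camera adjusted p = 0.000680; adjusted p = 0.364 with an estimated correlation). Besides Il17a and Il17f, Maf fell from 229 ± 68.4 to 77.0 ± 8.49 CPM (log2 fold change -1.57, SE 0.25, edgeR adjusted p = 0.0246). Il1r1 fell from 32.9 ± 12.6 to 9.56 ± 2.99 CPM (-1.78, SE 0.34, edgeR adjusted p = 0.0261). Of 18 pathogenic genes, 4 fell (10 adjusted over the list alone, camera adjusted p = 0.00868; adjusted p = 0.326 with an estimated correlation). Among them were the Th1 lineage factor Tbx21 (30.2 ± 9.20 against 78.0 ± 29.4 CPM) and the chemokine genes Ccl3 (51.1 ± 55.8 against 352 ± 170) and Cxcl3. Cxcl3 had 2 counts in the knockout, a ratio of wild type to knockout of 29.8 (95% interval 7.94 to 251), and counts in chemokine families are uncertain. The non-pathogenic list fell as well (2 of 8 called, 3 adjusted over the list alone, camera adjusted p = 0.0253; adjusted p = 0.284 with an estimated correlation), but not without knockout library 2 (camera adjusted p = 0.0769, of 0.0060 to 0.284 over all alternatives). Genes of IL-1, IL-6 and IL-23 signalling were not called as a set (1 of 17 fell, camera adjusted p = 0.304).

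Other T cell programs and markers of other cell types were also lower. In the regulatory T list 5 genes fell and 1, the folate receptor family gene Izumo1r, rose of 14 (7 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.0137; adjusted p = 0.326 with an estimated correlation). The transcription factor Ikzf2 fell from 44.3 ± 19.0 to 2.90 ± 1.80 CPM (log2 fold change -3.91, SE 0.48, edgeR adjusted p = 0.0222). Foxp3 had 3 counts in the knockout, a ratio of wild type to knockout of 91.2 (30.9 to 445). Th2 genes fell as a set (2 of 10 called, 5 adjusted over the list alone, camera adjusted p = 0.000606; adjusted p = 0.326 with an estimated correlation). The called members, named after their values were seen, were the cytokine genes Il5 (3 counts in the knockout, ratio of wild type to knockout 16.4, 5.33 to 81.9) and Il13 (3.85 ± 1.80 against 45.3 ± 22.5 CPM). B cell genes fell as a set (3 of 6 called, 4 adjusted over the list alone, camera adjusted p = 0.000125; adjusted p = 0.276 with an estimated correlation). Cd79a was at 1.67 ± 0.508 against 13.2 ± 4.88 CPM and Ebf1 was not called (log2 fold change -0.66, edgeR adjusted p = 0.149). CD8 T and NK genes fell as a set (2 of 6 called, 5 adjusted over the list alone, camera adjusted p = 0.00736; adjusted p = 0.276 with an estimated correlation). Prf1 was at 3.91 ± 0.978 against 14.2 ± 7.36 CPM and Cd8b1 was not called (log2 fold change 0.23, edgeR adjusted p = 0.676). Myeloid genes were not called (0 of 7, camera adjusted p = 0.457). Cd68, Lyz2 and Cd14 had edgeR adjusted p = 0.224, 0.969 and 0.915. The list was called without wild-type library 1 (camera adjusted p = 0.0379) or knockout library 1 (0.0347), of 0.035 to 0.581 over all alternatives. The Th1 list (3 of 14 fell, camera adjusted p = 0.327), which holds Il12rb2 (log2 fold change -0.64, edgeR adjusted p = 0.0466), and the Tfh list (3 fell and 1 rose of 8, camera adjusted p = 0.147) were not called. Ifng, Gzma and Foxp3, a trio chosen after its values were seen, summed to 0.706 and 7.25 CPM with the control vector, 0.406 and 7.86 in the knockout, and 140 and 326 in wild type.

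Proliferation and metabolic genes rose in the knockout. Cholesterol synthesis genes rose, 16 of 18 (17 adjusted over the list alone, mean log2 fold change 1.00, camera adjusted p = 3.29e-08; adjusted p = 0.326 with an estimated correlation). Hmgcs1, an early enzyme of that pathway, went from 177 ± 6.81 to 505 ± 122 CPM (log2 fold change 1.51, edgeR adjusted p = 0.0246). Like Ccnb2, Hk1, Irf7 and Ifi44, it was named after its values were seen. Cell cycle genes rose, 12 of 25 (13 adjusted over the list alone, mean 0.85, camera adjusted p = 0.000244; adjusted p = 0.526 with an estimated correlation). The mitotic cyclin gene Ccnb2 was at 77.7 ± 21.8 against 14.4 ± 0.220 CPM. Glycolysis genes rose, 6 of 18 (14 adjusted over the list alone, camera adjusted p = 6.67e-05; adjusted p = 0.379 with an estimated correlation). The hexokinase gene Hk1 was at 389 ± 102 against 184 ± 5.58 CPM. Replication-dependent histone genes rose, 7 of 13 (7 adjusted over the list alone, camera adjusted p = 5.12e-06, and 0.265 with an estimated correlation). Whether the selection of polyadenylated RNA shaped these counts was not tested. H2afx, the variant phosphorylated at DNA breaks, was at 86.1 ± 21.9 against 26.1 ± 3.85 CPM. Interferon-stimulated genes rose, 4 of 13 (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0146; adjusted p = 0.518 with an estimated correlation). Irf7 was at 28.9 ± 8.68 against 7.16 ± 2.20 CPM and Ifi44 at 16.5 ± 5.78 against 2.02 ± 0.788. The interferon list was not called without overexpression library 1 (camera adjusted p = 0.0771) or 2 (0.0737), wild-type library 1 (0.0589) or knockout library 2 (0.0769), of 0.0074 to 0.518 over all alternatives.

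The remaining lists were not called in the knockout. Of 14 Foxo1-dependent genes, 4 rose (5 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.132), Klf2 and the cyclin gene Ccng2 (111 ± 32.5 against 36.3 ± 7.76 CPM) among them. Of 13 reported miR-96 targets, 1 rose, Odf2 (107 ± 22.0 against 57.2 ± 10.1 CPM, camera adjusted p = 0.855 for the list). Of 18 reported miR-182 and miR-183 targets, 2 fell, Ccnd2 (945 ± 356 against 2221 ± 231 CPM) and Rasa1 (125 ± 38.2 against 246 ± 17.5), with camera adjusted p = 0.372 for the list. Camera adjusted p was 0.102 for naive or memory genes (3 rose and 1 fell of 12), 0.995 for immediate early genes (2 rose and 2 fell of 13, mean log2 fold change 0.06 with the test on the lower side) and 0.700 for endoplasmic reticulum stress (0 of 14 called). The naive or memory list was called without wild-type library 1 (camera adjusted p = 0.0464) and without a filter on low counts (0.0448), of 0.0039 to 0.326 over all alternatives. Camera called 12 of 22 lists, 0 with an estimated correlation, and fry called 7 for movement in 1 direction, the naive or memory list among them, and 20 for change in either direction, all but the Th1 and myeloid lists.

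Genes with a 3′ UTR site for any of the 3 microRNAs (3007 genes) lay lower in the knockout than the 8402 genes without, by a median log2 difference of -0.093 (camera adjusted p = 0.161). Of 1000 random triples of 7-mers with the same base compositions, 879 (87.9%) gave a value as low. By site the differences were -0.069 for miR-96 (camera adjusted p = 0.422), -0.12 for miR-182 (0.161) and -0.12 for miR-183 (0.161). Matched on 3′ UTR length the difference turned to 0.024, with 69.6% of triples as low.

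The 2 contrasts were set against each other, since one adds miR-96 and the other removes the cluster. The difference between them passed the test in 1070 of 11851 genes, 543 higher and 527 lower with miR-96, with 3537 at an unadjusted p under 0.05. The smallest p belonged to Jchain (difference of log2 fold changes 13.10, SE 0.87, edgeR adjusted p = 0.00133), Il10 (13.02, SE 0.96, 0.00172), Cd79a (7.06, SE 0.62, 0.00426), Foxp3 (11.64, SE 1.06, 0.00426) and Dhx58, an antiviral RNA helicase gene (-3.19, SE 0.29, 0.00426). The fitted differences of Jchain and Foxp3 rest on 3 counts in 1 of the groups. Dhx58 rose in the knockout (log2 fold change 2.07, edgeR adjusted p = 0.0211) and was not called with miR-96 (-1.12, 0.152). Of the 13 genes that rose with miR-96, 5 fell in the knockout (Cd79a, Erdr1, Foxp3, Il10 and Jchain), where independent lists give 0.831 (Fisher exact test, two-sided, p = 0.000883), and 1, Ctse, rose (0.862 for independent lists, p = 0.590). Across 11851 genes the log2 fold changes correlated with r = -0.309 and rho = -0.294, and in the 1544 genes called in the knockout r was -0.685 and 86.7% had opposite signs, against 61.6% of all tested genes. The Fisher exact tests and these correlations are across genes, which are not independent replicates. In log2 CPM, overexpression library 1 correlated at 0.982 and 0.978 with wild-type libraries 1 and 2, against 0.973 and 0.974 with control vector libraries 1 and 2. For overexpression library 2 the values were 0.964 and 0.956 against 0.957 and 0.947. Opposite signs thus cannot be told apart from a likeness of overexpression and wild-type libraries that does not come from miR-96. Of the genes that overlapped, Cd79a, Foxp3, Il10 and Jchain belong to the set of 16 genes low in both control vector libraries. They thus did not vary separately. The number of differing genes was 343 without control vector library 1, 451 without overexpression library 2, 151 and 23 without wild-type libraries 1 and 2, 25 without knockout library 1 and 1613 without knockout library 2. The correlation r was -0.089 without control vector library 1, -0.18 without overexpression library 1 and -0.17 without wild-type library 2, and rho was -0.010, -0.081 and -0.22. Without control vector library 2 and overexpression library 2, rho was -0.48 and -0.52.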

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

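The tests of donor sex and of the region around the cluster were chosen before their results were seen, and all the others in this part only after.

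The difference between the miR-96 and knockout contrasts passed the test in 1070 genes, a difference between the effects of the 2 experiments. Mir96 had a signal outside the tested genes, with 7 counts in overexpression library 1 and 2 in library 2 and 0 in both control vector libraries.

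Genes near 0 in both control vector libraries were present with miR-96 and in wild type, and Il10, Jchain, Foxp3 and Cd79a, which lead the difference between the contrasts, are among them. An effect of miR-96 as the cause of the whole pattern is argued against by the wild-type libraries, which the labels do not give as transduced with miR-96 but which stood above the control vector by 1.04 times the median log2 difference of the overexpression libraries over the 13 called genes, where 20 simulated draws with wild type equal to the same control vector libraries gave -0.088 to 0.128 (mean -0.0075). Any 1 source as the only source of these transcripts in all libraries, B cells or plasma cells included, is argued against by the knockout libraries, where the levels of 16 genes of this pattern relative to wild-type library 2 spread widely (upper over lower quartile 53.2 and 27.1), while B cells as part of the material stay open. A candidate explanation is material from 1 shared source in both overexpression libraries and wild-type library 1, where the level of the 16 genes relative to wild-type library 2 was nearly 1 ratio per library (upper over lower quartile at most 1.21) and Y-linked genes had that ratio to within 1.05-fold in overexpression library 1 and wild-type library 1. In overexpression library 2 the Y-linked ratio was 1.34, 2.96-fold from the 0.454 of the 16 genes, so such a source alone is argued against for its Y-linked transcripts, and what the source was, and whether cells or RNA were mixed, stays open.

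Many genes were called in the knockout, and the wild-type libraries are part of the first pattern. The share of X and Y genes among the calls was 0.744 times that of other genes (39 of 389), so the calls did not gather there. This does not test effects of sex on genes of other chromosomes, so the sex of the animals stays open. The fractional counts of knockout library 1 stay open: genes with fractional and whole values there differed by a median of -0.025 (log2) between the knockout libraries, which decides nothing where genes move both ways, and 15.1% against 9.53% of them were called. Material in the wild-type libraries cannot be told apart from an effect of the knockout for the 1544 called genes as a set: the knockout differed from the control vector by 0.463 times its difference from wild type in the direction of the call (medians 0.46 and 0.99, log2), a value between what either would give, and both differences share the knockout libraries. An effect of losing the cluster also stays open.

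Genes near the cluster could carry variants along with the targeted locus. Of 66 tested genes within 10 Mb, 4 were called, 0.464 times the share elsewhere (Fisher exact test, two-sided, p = 0.0996), which argues against a gathering of calls there.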

How the results depend on the processing

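Leaving out sex-linked genes or both genotype libraries numbered 1 was chosen after seeing the data, as was the rank of the length-matched site value. The miR-96 count of 13 genes became 466 without a filter, 8 with only the 4 libraries of the contrast, 8 without sex-linked genes and 113 with DESeq2, and 0 to 125 with a library left out. The knockout count of 1544 became 3151 without a filter, 2641 with only its 4 libraries, 1 without both genotype libraries numbered 1, and 0 to 1975 with a library left out. The count of 1070 differing genes became 2534 without a filter, 1647 with DESeq2 and 23 to 1613 with a library left out. Where a library was left out, the lone sample of its group is assumed to vary like those of the other groups. Lists called with miR-96 (13) became 0 with an estimated correlation and 4 with fry in 1 direction, and 10 to 14 with a library left out. In the knockout (12) they became 0 with an estimated correlation, 7 and 20 with fry in 1 or either direction, and 10 to 13 with a library left out. The miR-96 site difference became 0 without a filter, -0.0038 with 8-mer sites and -0.044 matched on length, and -0.016 to 0.046 with a library left out, and that of the knockout (-0.093) -0.034 without a filter, 0.024 matched on length and -0.10 to -0.081 with a library left out. The correlation of the contrasts became -0.149 without a filter, -0.165 with DESeq2 and -0.400 to -0.0888 with a library left out. Fewer samples leave less power, but less power alone would not raise the counts that rose with a library left out. The cause was not tested further.

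Duplicates with the same number did not deviate together (correlation -0.221 in the transduced and 0.0953 in the genotype experiment). With the duplicate number as a block, 15 genes were called with miR-96 (9 shared), 477 in the knockout (457 shared) and 449 for the difference (430 shared), and 13 lists were called in each of the 2 comparisons. In that fit Foxp3 and Cd79a were not called with miR-96. Named genes not called in the knockout included Itga7, Acvrl1, Tubb2b, Mgarp and Cxcl3. The naive or memory list was called there (camera adjusted p = 0.0411).

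Other scalings and the 1 CPM filter left the gene counts within 1.5 times. Of the knockout's named genes over all alternatives, 673 of 848 comparisons kept their direction and side of the threshold, 169 lost a call and 6 gained 1, and with miR-96 489, 26 and 39 of 554. For single lists 337 of 374 were kept in the knockout (23 lost, 14 gained) and 331 of 374 with miR-96 (36 lost, 7 gained). Depth limits genes with few counts, such as Mir96.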

Other observations

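The lists in this part were chosen only after the data were seen and were adjusted over 8 tests. Guanylate-binding and immunity-related GTPases, which interferon gamma induces, rose as a set with miR-96 (0 of 16 called, camera adjusted p = 9.27e-05; adjusted p = 0.295 with an estimated correlation) and fell in the knockout (6 of 16 called, camera adjusted p = 0.000122; adjusted p = 0.295 with an estimated correlation). Counts within this family are uncertain. Plasma cell genes rose as a set with miR-96 (1 of 7 called, camera adjusted p = 5.13e-06; adjusted p = 0.119 with an estimated correlation) and fell in the knockout (3 of 7 called, camera adjusted p = 0.000221; adjusted p = 0.134 with an estimated correlation).

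Fatty acid synthesis genes fell as a set with miR-96 (0 of 13 called, camera adjusted p = 0.00133; adjusted p = 0.295 with an estimated correlation) and rose in the knockout (5 of 13 called, camera adjusted p = 0.0204; adjusted p = 0.295 with an estimated correlation), where the desaturase gene Fads2 had a log2 fold change of 2.41 and the acetyl-CoA synthetase gene Acss2 of 2.24. Hypoxia-responsive genes rose as a set in the knockout (2 of 13 called, camera adjusted p = 0.00113; adjusted p = 0.295 with an estimated correlation) and were not called with miR-96 (camera adjusted p = 0.577).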
